A study of Mus musculus with 4 samples.

How the data were processed

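Chromatin immunoprecipitation and sequencing (ChIP-seq) was done on whole mouse uterus at 2 stages, with an antibody to FOXA2 and an antibody to RNA polymerase II phosphorylated on serine 2 of its C-terminal repeat (POL2 in the labels). The stages were postnatal day 12 (PD12) and the adult uterus in pseudopregnancy, labelled with days 2.5 and 3.5 on a single library, and how the days were combined is not given in the sources used here. Each of the 4 groups of antibody and stage had 1 library. There were therefore no replicates, no test between stages was possible, and no p-value is given.

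Per the labels' protocols, tissue was fixed in formaldehyde, sonicated and precipitated with a goat polyclonal antibody (FOXA2) or a rabbit polyclonal antibody (POL2), and input DNA was prepared as well. BWA was used, per the submitters' processing notes, which name no version. The peak caller, its threshold, the use of the input and the genome build are not given in the sources used here. Per the file headers, each deposited list holds the chromosome, start and end of called intervals. The lists carry no height, score, enrichment or read count, so the depth of each library is unknown and intervals could not be ranked by strength. The number of intervals called depends on depth and threshold, so list lengths are described here as lengths of lists. In whole uterus it can also depend on the share of cells with FOXA2, which is not known here. All POL2 starts lay on a grid of 200 bp with at least 800 bp between neighbours, whereas 0.737% of PD12 and 0.559% of adult FOXA2 starts lay on that grid. Because the lists of the 2 antibodies differ in this way, widths were compared within an antibody.

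Positions are given as in the files, counted as inclusive, so that width is end minus start plus 1. The build is unnamed. The intervals were compared with the gene table at hand, which is for GRCm38, and 260 intervals on 9 of 20 chromosomes lay beyond the last GRCm38 gene, 177 of them on chromosome 7. Adult POL2 centres lay in GRCm38 coding genes at 54.6%, against at most 43.8% after 100 shifts. Because of the intervals beyond the last genes, the files were taken not to be on GRCm38, although chromosome lengths were not compared. Neither an annotation nor a sequence of their own build was used here. The exon, intron or gene at each region is for that reason not stated. The planned analyses of peak location, of the forkhead motif, of FOXA2-bound and POL2-occupied genes and of 18 gene lists were not run.

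Intervals were called shared when they overlapped by at least 1 bp. An interval with no overlap in the other stage's list for the same antibody is called PD12-only or adult-only, which describes the lists and not the absence of binding. Each share has an exact (Clopper-Pearson) 95% binomial interval. Chance overlap was taken from 1000 circular shifts of one list along each whole chromosome. It was taken again from 1000 shifts of 50 to 500 kb. These keep regional density at scales above 500 kb, keep it only in part between 50 and 500 kb, and do not keep density below 50 kb. Folds are observed counts over the mean of the shifts, with exact Poisson 95% limits, and a ratio of 2 folds has a 95% interval from the exact binomial split of the counts. All these intervals cover counting error alone, and intervals within a list are not replicates. Shared bases were compared with 20 shifts, and shares in bins of width with 200 shifts. The calculation was tested on simulated lists. With 50% of PD12 FOXA2 intervals planted in a list like adult FOXA2, 50.1% were recovered, and with 50% of PD12 POL2 domains planted in a list like adult POL2, 53.8% were recovered, where shifts gave 8.73%. With none planted, folds were 0.744 and 0.986 for these comparisons and 0.995 for adult FOXA2 in a list like adult POL2. The simulated lists were themselves made by circular shifts. They therefore check the calculation only, and not whether shifts are a fair model of chance.

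The comparison of stages for each antibody, the 1 bp overlap, the whole-chromosome shifts, and the alternatives of a 50% overlap of both intervals and of centres within 500 bp were fixed before the data were examined. The rule for what the text names was fixed then. It took the genes at the 10 highest-ranked FOXA2 intervals of each class, ranked by width where no score is given, the 10 genes with the most POL2-covered bases of each class, Foxa2 itself and bound members of the gene lists. Without genes it was applied to the regions themselves, the 10 widest of each class. The overlap of FOXA2 intervals with POL2 domains replaced the planned comparison of genes and was chosen after the files were read, as were the alternatives based on width, on merging domains across gaps of up to 5 kb, on centres inside domains and on shifts of 50 to 500 kb. The planned stricter threshold and equal list length by the authors' score had no score to use, and width took its place. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.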

Results

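FOXA2, a forkhead transcription factor of the glandular epithelium of the uterus, was profiled in whole mouse uterus during postnatal gland development (PD12) and in the adult in pseudopregnancy, the hormonal state that follows a sterile mating. RNA polymerase II phosphorylated on serine 2, the form found on gene bodies during elongation, was profiled at the same stages. The series asked where FOXA2 binds in the developing and in the adult uterus. Each group had 1 library, so no difference between stages has a replicate check. The FOXA2 lists held 814 intervals at PD12 (median width 318.5 bp, interquartile range 263 to 394) and 10373 in the adult (685 bp, 560 to 821). The POL2 lists held 9972 intervals at PD12 (median 5400 bp, 3400 to 8800) and 14818 in the adult (4800 bp, 2800 to 8000), called domains here because of their width. FOXA2 intervals covered 0.291 Mb at PD12 and 7.63 Mb in the adult, and POL2 domains covered 70.4 and 95.2 Mb. Read depth is unknown for all 4 libraries, and so is the share of cells with FOXA2 at each stage. Because whole uterus was used, overlap of a FOXA2 interval with a POL2 domain does not show both in the same cells.

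The first comparison asked whether FOXA2 occupied the same regions at both stages. Most regions listed at PD12 were also listed in the adult, whereas the adult list held 12.7 times as many intervals. Of the 814 PD12 intervals, 587 (72.1%, 95% interval 68.9 to 75.2) overlapped an adult interval, against a mean of 0.469% and a highest value of 1.35% after shifts. Of the 10373 adult intervals, 586 (5.65%, 5.21 to 6.11) overlapped a PD12 interval, and 9787 were adult-only. The shared intervals lay close to each other, with a median of 56 bp from a PD12 centre to the nearest adult centre, and 73.4% (69.7 to 77.0) of them lay within 100 bp.

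The widest shared FOXA2 region was at chromosome 17, 39979544 to 39985889, a single adult interval of 6346 bp in which PD12 had 2 intervals covering 5346 bp. An adult POL2 domain with nearly the same ends, 39979800 to 39985799, was listed there, and no PD12 one. The next were at chromosome 12, 77469888 to 77472724 (2837 bp in the adult, 475 bp of it listed at PD12), chromosome 4, 133369009 to 133371581 (2573 and 533 bp), and chromosome 1, 36612722 to 36615249 (2528 and 516 bp). The widest adult-only FOXA2 intervals were at chromosome 17, 34255699 to 34259947 (4249 bp), chromosome 11, 68935456 to 68939145 (3690 bp), and chromosome 6, 38482480 to 38485335 (2856 bp). The first of these lay in POL2 domains of both stages, the second in none, and the third in an adult POL2 domain alone. Among the 10 widest adult-only FOXA2 intervals, 7 lay in a PD12 POL2 domain and 8 in an adult one. The nearly equal ends of FOXA2 and POL2 on chromosome 17 leave signal independent of the antibody possible. No named region was checked for that or for repeated sequence.

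PD12-only FOXA2 intervals numbered 227, and 43 of them (18.9%, 14.1 to 24.7) had an adult FOXA2 interval within 10 kb. This share was above the mean of whole-chromosome shifts (8.16%) and equalled the highest of the shifts of 50 to 500 kb (mean 12.3%). The 2 widest PD12-only intervals lay together on chromosome 2, at 77810425 to 77815562 (5138 bp) and 77762666 to 77765302 (2637 bp). The next, at chromosome 1, 88383745 to 88384728, was 984 bp wide and lay in POL2 domains of both stages. PD12-only and shared PD12 intervals had similar median widths, of 328 and 315 bp.

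Adult FOXA2 intervals that were shared with PD12 were wider (median 805 bp) than adult-only ones (679 bp). Split by width into 10 equal bins, 2.12% (1.33 to 3.19) of the narrowest adult intervals and 9.92% (8.17 to 11.9) of the widest overlapped a PD12 interval, with the highest share, 11.9% (9.96 to 14.0), in the bin next to the widest. Wider intervals touch another list more often by their length alone. No shifts were run for this share by width, so the part due to length is not known. PD12 intervals, in 5 equal bins, did not show a rise with width. Their shared part was 69.3% (61.6 to 76.3) in the narrowest bin, 79.0% (71.9 to 85.0) in the middle and 62.6% (54.7 to 70.0) in the widest. When 50% of both intervals had to be covered, 15.5% of PD12 and 1.21% of adult intervals were shared, and the median PD12 interval is itself shorter than 50% of the median adult one. Against the 814 widest adult intervals, 10.8% of PD12 intervals were shared, and between the 50% widest intervals of each list 59.5% were.

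The second comparison asked which regions carried elongating polymerase at each stage. Most PD12 POL2 domains were also listed in the adult, and the adult list added 6758 domains with no PD12 counterpart. Of 9972 PD12 domains, 7965 (79.9%, 79.1 to 80.7) overlapped an adult domain, 10.7 times the mean of the shifts (7.45%), and 2007 were PD12-only. Of 14818 adult domains, 8060 (54.4%, 53.6 to 55.2) overlapped a PD12 domain. The stages shared 50.7 Mb, which was 72.0% of the bases covered at PD12 and 53.2% of those covered in the adult, 17.6 times the mean of the shifts.

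The widest POL2 domain was at chromosome 1, 170074000 to 170364599, where a single adult domain of 290.6 kb faced 13 PD12 domains covering 266.8 kb. Other wide adult domains with nearly full PD12 coverage were at chromosome 16, 14187400 to 14285599 (98.2 kb, 92.6 kb of it covered at PD12), and chromosome 9, 8897800 to 8990399 (92.6 and 88.4 kb). At chromosome 10, 87320400 to 87403999, an adult domain of 83.6 kb had 9.6 kb covered at PD12 and held 3 adult FOXA2 intervals. The opposite was seen at chromosome 8, 91043600 to 91129199, where a PD12 domain of 85.6 kb had 7.4 kb covered in the adult and held 2 PD12 FOXA2 intervals and no adult one. That was the lowest adult coverage among the 10 widest shared PD12 domains. The widest of them, at chromosome 18, 69764600 to 69853999 (89.4 kb), had 86.2 kb covered in the adult.

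The widest adult-only POL2 domains were at chromosome 9, 48523800 to 48597799 (74.0 kb), chromosome 5, 107610400 to 107684199 (73.8 kb), chromosome 15, 66938400 to 66995799 (57.4 kb), chromosome 13, 24784200 to 24832799 (48.6 kb), and chromosome 19, 24061000 to 24106599 (45.6 kb). The first held 3 adult FOXA2 intervals and each of the others held 1. PD12-only domains reached smaller widths, the widest being at chromosome 19, 56978600 to 57010599 (32 kb), chromosome 10, 5716000 to 5736999 (21.0 kb), and chromosome 11, 59562800 to 59583799 (21.0 kb). Of the 10 widest domains of each class, 5 adult-only and 1 PD12-only domains held an adult FOXA2 interval, and none of the 20 held a PD12 one.

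**Figure D1:**
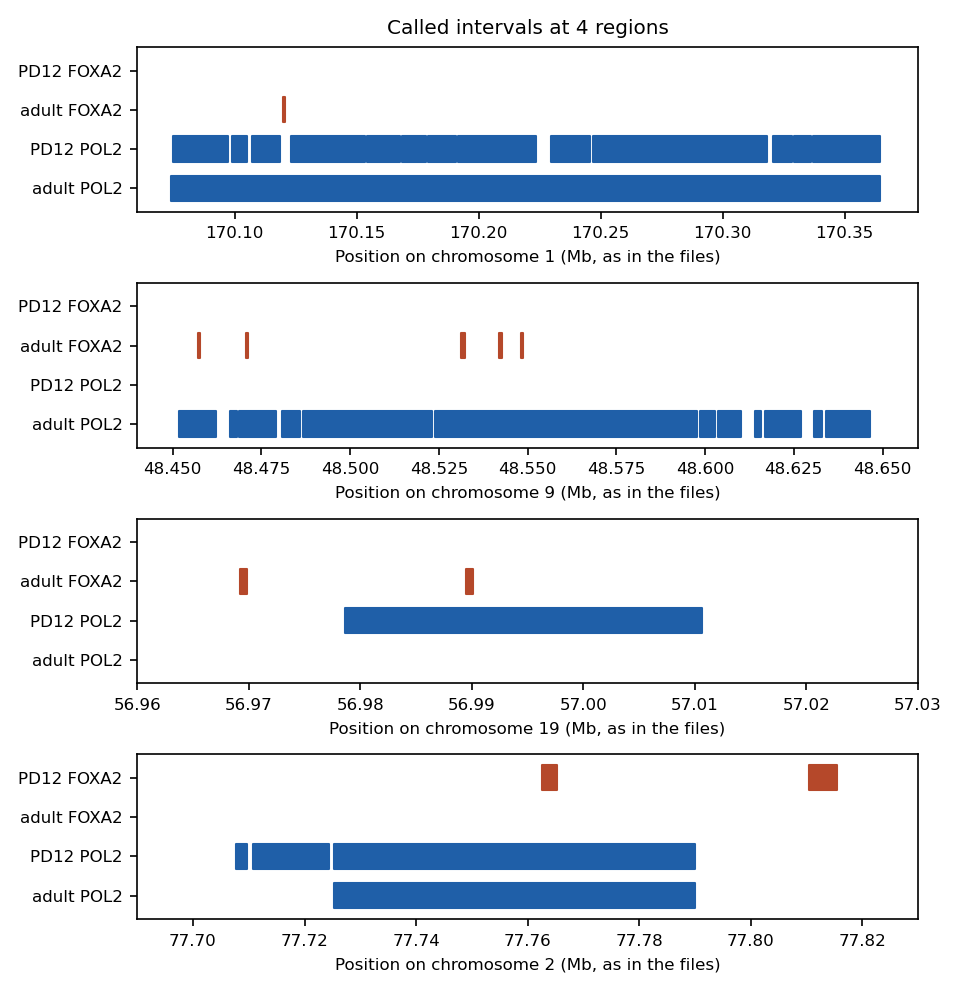
Called intervals at 4 regions, with position in Mb along the horizontal axis and the 4 lists as rows (FOXA2 in red, POL2 in blue). The regions are the widest POL2 domain (chromosome 1), the widest adult-only domain with its neighbours (chromosome 9, 12 adult domains covering 175.2 kb and 5 adult FOXA2 intervals, none at PD12), the widest PD12-only domain (chromosome 19, 32 kb), and the 2 widest PD12-only FOXA2 intervals, one inside and one outside a POL2 domain of 64.8 kb listed at both stages (chromosome 2).

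PD12-only and adult-only domains had the same median width (3400 bp, interquartile range 2000 to 5400), below those of shared domains (6000 bp at PD12 and 6400 bp in the adult). The share of adult domains overlapping a PD12 domain went from 17.3% (15.4 to 19.4) in the narrowest 10% to 90.1% (88.5 to 91.6) in the widest 10%, and at PD12 from 49.0% (45.9 to 52.1) to 97.2% (96.0 to 98.1). Wider domains touch another list more often by their length alone. No shifts were run by width for POL2, so the part due to length is not known. With an overlap of 50% of both domains the shares were 51.1% of PD12 and 34.4% of adult domains. With centres within 500 bp they were 21.7% and 14.6%.

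The third comparison set FOXA2 intervals against POL2 domains of the same stage. About 1 in 5 FOXA2 intervals lay in a POL2 domain at either stage, several times more than after shifts, and most lay in none. At PD12, 165 of 814 (20.3%, 17.6 to 23.2) overlapped a PD12 domain, 6.39 times (5.46 to 7.45) the mean of whole-chromosome shifts and 3.67 times that of shifts of 50 to 500 kb. In the adult, 2012 of 10373 (19.4%, 18.6 to 20.2) overlapped an adult domain, 4.41 times (4.22 to 4.61) and 2.82 times the means of the shifts. POL2 domains of neither stage held 549 PD12 intervals (67.4%, 64.1 to 70.7) and 8226 adult intervals (79.3%, 78.5 to 80.1).

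FOXA2 regions and POL2 domains were also compared across stages. PD12 FOXA2 intervals overlapped adult POL2 domains in 243 cases (29.9%, 26.7 to 33.1), 6.97 times the mean of whole-chromosome shifts. Adult FOXA2 intervals overlapped PD12 domains in 1185 cases (11.4%, 10.8 to 12.1), 3.55 times that mean. The 227 PD12-only FOXA2 intervals lay in adult POL2 domains in 82 cases (36.1%, 29.9 to 42.7) and the 587 shared ones in 161 (27.4%, 23.9 to 31.2). The limits overlapped, which does not show that the shares are alike, and the difference was not tested. FOXA2 centres inside domains were not gathered at domain ends. In the adult, 37.0% (34.8 to 39.1) lay within 1 kb of an end, against 39.5% for uniform placement, and at PD12 28.0% (21.3 to 35.6) against 31.2%. For the widest 10% of adult intervals it was 31.7% (28.1 to 35.4) against 38.7%, below uniform placement.

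Wide FOXA2 intervals lay in POL2 domains far more often than narrow ones. In the adult the share was 6.45% (5.04 to 8.13) in the narrowest 10% and 63.2% (60.2 to 66.1) in the widest 10%, while the mean of shifts of 50 to 500 kb went from 4.88% to 10.8%. At PD12, in 5 equal bins, it went from 5.52% (2.56 to 10.2) to 44.2% (36.4 to 52.1). Wide intervals also lay in POL2 domains of the other stage, at 70.6% (62.9 to 77.4) for the widest 20% of PD12 intervals in adult domains and 39.4% (36.4 to 42.5) for the widest 10% of adult intervals in PD12 domains. The first share was above that in domains of the same stage, and the second was below it. Shifts by width were not run for domains of the other stage. In the 50% narrowest intervals the share in domains of the same stage was 10.1% at PD12 and 8.58% in the adult. With the adult lists reduced to their widest intervals, as many as at PD12, the adult share was 51.2%.

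**Figure D2:**
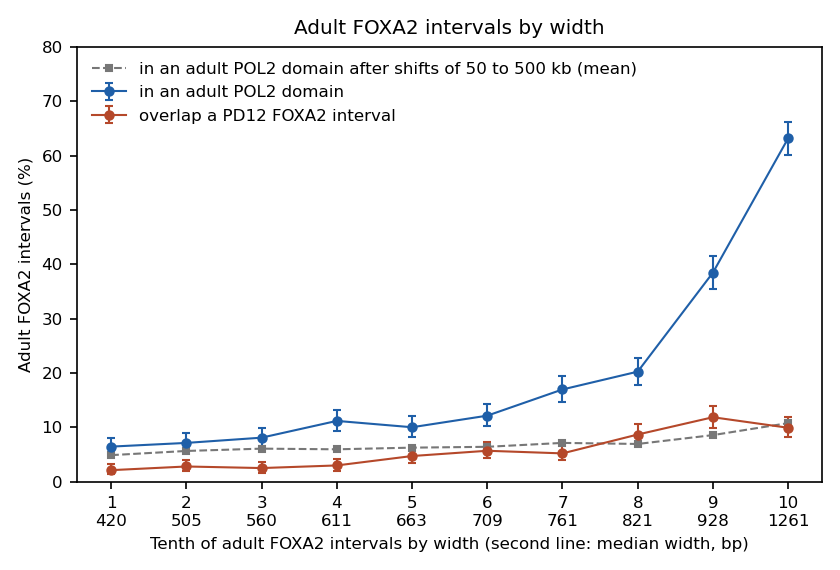
Adult FOXA2 intervals in 10 bins of equal size by width (horizontal axis, with the median width in bp), with the share in % on the vertical axis. Blue points are intervals in an adult POL2 domain, red points are intervals overlapping a PD12 FOXA2 interval, bars are exact 95% binomial intervals, and grey squares are the mean share in POL2 domains after shifts of 50 to 500 kb, and the blue share goes from 6.45% to 63.2%.

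POL2 domains listed in the adult alone held more FOXA2 intervals, relative to shifts, than domains listed at PD12 alone. Adult-only domains held 790 adult FOXA2 intervals, 5.50 times (5.12 to 5.89) the mean of whole-chromosome shifts, and PD12-only domains held 78, 1.88 times (1.48 to 2.34). Shared adult domains, which are wider, lay between them at 3.91 times (3.69 to 4.13). Against shifts of 50 to 500 kb these folds were 3.64 (3.39 to 3.90) for adult-only, 1.23 (0.975 to 1.54) for PD12-only and 2.46 (2.32 to 2.60) for shared domains, so for adult FOXA2 the PD12-only domains were not distinguishable from their surroundings. An adult FOXA2 interval was present in 11.1% (10.4 to 11.9) of adult-only domains, 3.69% (2.91 to 4.61) of PD12-only domains and 13.6% (12.8 to 14.4) of shared adult domains. PD12 FOXA2 intervals numbered 84 in adult-only domains, 8.0 times (6.38 to 9.91) the mean of the shifts, and 12 in PD12-only domains, 3.98 times (2.06 to 6.96). Against shifts of 50 to 500 kb these were 5.32 times (4.24 to 6.59) and 2.17 times (1.12 to 3.78).

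The ratio of the adult-only to the PD12-only fold was 2.93 (2.32 to 3.75) for adult FOXA2 and 2.01 (1.09 to 4.04) for PD12 FOXA2. For adult FOXA2 it was 1.76 (1.17 to 2.75) in the 50% narrowest intervals, and 1.21 (0.709 to 2.19) when these were set against domains of 5 kb or more with shifts of 50 to 500 kb, an interval that includes 1. For PD12 FOXA2 it was 1.02 (0.397 to 3.08) in the 50% narrowest intervals and 0.916 (0.352 to 2.80) in domains of 5 kb or more. With shifts of 50 to 500 kb, the adult FOXA2 ratio was 3.97 (2.84 to 5.70) in domains under 5 kb and 2.05 (1.48 to 2.92) in wider ones, and the PD12 FOXA2 ratio was 3.55 (1.55 to 10.04) and 1.17 (0.451 to 3.59). The intervals of narrow and wide domains overlapped for both lists, for adult FOXA2 only between 2.84 and 2.92. Such an overlap does not show that the ratios are alike, and the difference between them was not tested.

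**Figure D3:**
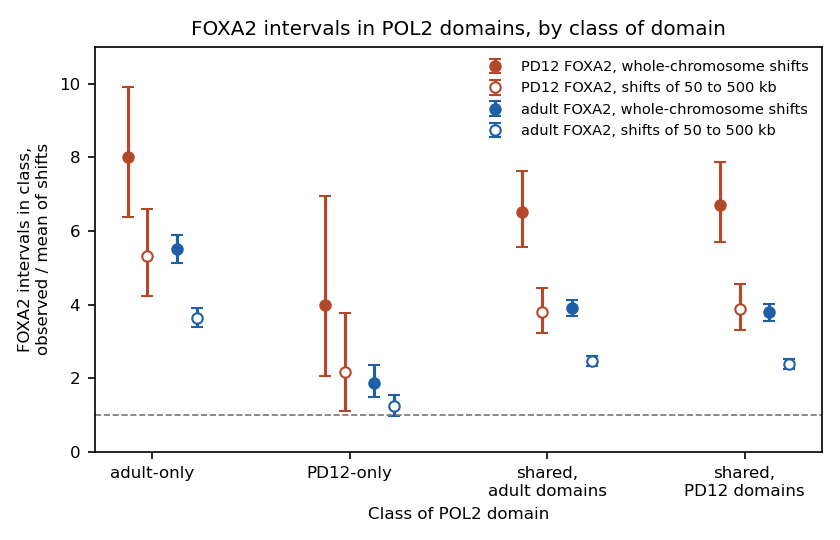
FOXA2 intervals in 4 classes of POL2 domain (horizontal axis), as the observed number over the mean of shifts (vertical axis), for PD12 FOXA2 (red) and adult FOXA2 (blue). Filled points are whole-chromosome shifts, open points are shifts of 50 to 500 kb, bars are exact Poisson 95% limits and the dashed line is a ratio of 1, and for adult FOXA2 the adult-only class stands at 5.50 and the PD12-only class at 1.88.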

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

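Of the alternatives here, those based on width, on merged domains, on centres inside domains, on domains under or over 5 kb and on shifts of 50 to 500 kb were chosen after the data were seen. Over 8 results and 43 alternatives, 18 values stayed within the 95% interval of the reported value, 24 moved outside it and 1 changed direction. FOXA2 overlap was 72.1% of PD12 and 5.65% of adult intervals. It was 15.5% and 1.21% with 50% of both intervals covered, 59.5% and 4.65% in the 50% widest intervals of each list, and 10.8% and 10.7% with the adult list reduced to its 814 widest. POL2 overlap was 79.9% of PD12 and 54.4% of adult domains. It was 51.1% and 34.4% with 50% of both covered, 21.7% and 14.6% with centres within 500 bp, and 68.7% and 66.1% at equal list length, while the PD12 share was 78.3% in the 50% widest domains and the adult share 56.4% with gaps of up to 5 kb merged. The reduced adult list differs from the full one in length and width together, and the cause of these differences was not tested. FOXA2 in POL2 domains was 20.3% at PD12 and 19.4% in the adult, 10.1% and 8.58% in the 50% narrowest FOXA2 intervals, and 51.2% in the adult at equal list length. The ratio of adult-only to PD12-only folds for adult FOXA2, 2.93, was 2.01 in domains of 5 kb or more and 1.76 in the 50% narrowest intervals. For PD12 FOXA2, 2.01, it was 0.916 and 1.02, resting on 6 intervals in PD12-only domains each time, and 1.69 (0.910 to 3.42) with gaps merged. In the 50% narrowest intervals and domains of 5 kb or more together, with shifts of 50 to 500 kb, the ratios were 1.21 for adult and 1.02 (0.245 to 5.97) for PD12 FOXA2. With those shifts and all intervals they were 3.97 and 3.55 in domains under 5 kb, and 2.05 and 1.17 in wider ones.

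No paired analysis was possible because each group has 1 library. The planned stricter threshold and equal list length by the authors' score were not run, nor were other settings for peak location, motif share, FOXA2-bound genes, POL2-occupied genes, FOXA2-bound genes with POL2 and gene lists. Unknown depth limits every comparison of list length, and the unknown mix of cells in whole uterus does so as well.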

Other observations

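The regions in this part were chosen after their values were seen, except those already named in the comparisons. The tests of regional density, of shared adult chromatin, of interval length, of both limits at once and of domains under 5 kb were chosen after the results were seen. POL2 domains of both stages were joined across gaps of up to 5 kb into 11353 stretches, and the length covered at each stage was compared. The stretch with the largest adult excess was at chromosome 9, 48451800 to 48646399, with 175.2 kb covered in the adult, none at PD12 and 5 adult FOXA2 intervals. Chromosome 5, 107524400 to 107718799, had 189.4 kb covered in the adult and 26.2 kb at PD12, with 4 adult FOXA2 intervals, and chromosome 6, 30999000 to 31171999, had 169.8 and 23.2 kb. At chromosome 19, 17781800 to 17912399, 108.6 kb was covered in the adult and none at PD12, with no FOXA2 interval of either stage. At chromosome 14, 120674400 to 120752399, the adult had 71.2 kb covered, PD12 4.4 kb, and 6 adult FOXA2 intervals were listed. The largest PD12 excesses were at chromosome 8, 91043600 to 91129199 (85.6 kb at PD12 and 7.4 kb in the adult), and chromosome 7, 137297800 to 137406399 (101.6 and 27.0 kb). A difference of 10 kb or more was found at 777 stretches toward the adult and 221 toward PD12, of which 33.1% (29.8 to 36.5) and 27.6% (21.8 to 34.0) held an adult FOXA2 interval. A PD12 FOXA2 interval was present in 3.47% (2.30 to 5.02) and 5.43% (2.84 to 9.29). For both lists the intervals of the shares overlapped, and the differences were not tested.

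Adult FOXA2 intervals gathered in groups. A neighbour within 10 kb was present for 22.4% (21.6 to 23.2) of them, against a mean of 8.76% and a highest value of 9.85% over 200 random placements, and for 4.18% (2.91 to 5.79) of PD12 intervals against a mean of 0.687%. Random placements do not keep regional density. Adjoining calls can also count as neighbours, and the smallest gap was 0 bp in the adult list and 250 bp at PD12. Windows of 100 kb with the most adult intervals included chromosome 13, 23600000 to 23699999, with 8 intervals beside 6 POL2 domains at each stage. Another was chromosome 7, 119900000 to 119999999, with 8 adult intervals, 1 PD12 FOXA2 interval, 1 PD12 POL2 domain and no adult one. At chromosome 16, 22438914 to 22470635, 6 adult intervals lay within 31.7 kb with no POL2 domain of either stage in the window. Chromosome X had few intervals in every list, with 0.862 adult FOXA2 intervals per Mb against 4.27 on autosomes, 7 PD12 FOXA2 intervals in all, and 1.84 adult POL2 domains per Mb against 6.05. Some wide FOXA2 regions had POL2 in the adult list and none at PD12. They included the widest shared region on chromosome 17 (adult POL2 domain of 6000 bp), chromosome 2, 98502293 to 98507605, with 2 FOXA2 intervals at each stage and 2 adult POL2 domains covering 4400 bp, and chromosome 11, 86570642 to 86571939, with 1 FOXA2 interval at each stage in an adult domain of 18600 bp. At chromosome 9, 2999887 to 3036721, the first listed stretch of that chromosome, 7 adult FOXA2 intervals and an adult POL2 domain of 2600 bp were listed and nothing at PD12. These regions were not checked for repeated sequence or for signal independent of the antibody either.

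Relative to shifts, FOXA2 intervals lay in adult-only POL2 domains more than in PD12-only ones. With 10 kb added at each side of the domains, the contrast was smaller. Domains with a FOXA2 centre were then 2.48 and 1.65 times the mean of whole-chromosome shifts for adult FOXA2. For PD12 FOXA2 they were 2.59 and 2.30 times. In the stretches above with a difference of 10 kb or more, adult FOXA2 shares were 33.1% and 27.6%. Those of PD12 FOXA2, 3.47% and 5.43%, went the other way. For adult FOXA2 the ratio of folds against shifts of 50 to 500 kb was 2.95 (2.33 to 3.77). This argues against regional density at scales above these shifts as the whole cause. Density at scales below 50 kb is not kept by them, and between 50 and 500 kb only in part, so both stay open. With these shifts the ratio was 1.75 (1.16 to 2.74) in the 50% narrowest intervals and 2.05 (1.48 to 2.92) in domains of 5 kb or more. Both values stayed above 1 but below 2.95. Wide FOXA2 intervals over transcribed chromatin, and weaker calls among PD12-only domains, may therefore each give a part. The lists carry no score, so width stood in for call strength, and neither limit sets its cause aside. With both limits at once the ratio was 1.21 (0.709 to 2.19), on 74 and 17 intervals. The pair of causes together therefore stays open. In domains under 5 kb the ratio was 3.97 (2.84 to 5.70). An artefact of the adult chromatin or its control cannot be told apart, because PD12 FOXA2, from other chromatin, gave 2.46 (1.34 to 4.94) over all intervals but 1.26 (0.492 to 3.81) in the 50% narrowest and 1.17 (0.451 to 3.59) in domains of 5 kb or more. A biological difference between the stages also stays open, and was not tested apart from these. The POL2 lists differed in length, with 14818 adult and 9972 PD12 domains. The ratio of folds was not computed at equal list length, so the part due to list length is not known.

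The share of adult FOXA2 intervals in POL2 domains was higher in wider intervals. Longer intervals touch domains more often, but 63.0% of the centres of the widest 10% lay in domains, against 5.97% (upper limit 7.59) in the narrowest 10%, so length alone does not give the difference. The fold over shifts of 50 to 500 kb was 5.88 in the widest 10% (4.62 against the highest shift) and 1.32 in the narrowest. Regional density at scales above these shifts does not give the difference either. Density at scales below 50 kb is not kept by such shifts, and between 50 and 500 kb only in part, so both stay open. Background precipitation from transcribed chromatin could give the same picture, as could stronger binding at active genes, and the lists carry no control or height to separate them.

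Of the 2 widest PD12-only FOXA2 intervals, on chromosome 2, 1 lay inside and 1 outside a POL2 domain, 77725200 to 77789999. The ends of this domain were identical in both stages. At PD12 another POL2 domain, 77710800 to 77724399, was listed just before it, and no adult one. The first end was therefore not the edge of the called PD12 signal. POL2 ends lie on a grid of 200 bp, so identical means the same step of that grid. Extra DNA copies in the animals relative to the reference could give sharp shared ends, and identical ends were found at 1.09% of PD12 domains of 20 kb or more (4 of 367) and at 0.820% (3 of 366) without this domain, where the explanation asked for at most 1%. It also asked for an adult FOXA2 interval in the domain, and the adult list had none there. It stays open with or without this domain in the count, because the ends of other domains cannot show whether copies are extra here. No biological explanation was tested.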
